A study of Danio rerio with 13 samples.

How the data were processed

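The measured quantity was the cDNA count per crosslinked nucleotide in iCLIP of zebrafish embryos of the AB strain, irradiated at 254 nm, per the labels' protocols. Lysates were treated with RNase I, complexes were pulled down with an anti-hnRNP A1 antibody or with IgG as the negative control, run on a gel and blotted, and RNA from above the size of the protein was reverse transcribed with barcoded primers. The barcode in the labels contains random positions, which can mark single cDNA molecules. The tables are named as cDNA counts, but how duplicates were removed is not given in the sources used here, so intervals cover counting error only.

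The authors deposited, per the labels, significant crosslink sites of the summed replicates of each group. The names of the tables give a false discovery rate of 0.01, 100 permutations, a neighbourhood of 15 nt and Ensembl release 72, on the zebrafish assembly Zv9. CASAVA version 1.4 and the build Zv9 are named in the submitters' processing notes. The aligner is not given in the sources used here. Unique-mapping tables hold whole cDNA counts, per the deposited values, and multi-mapping tables hold fractional counts in which 1 cDNA is shared over its genomic hits, down to 0.02. The sign of each deposited count gave the strand, which was checked on a copy of 1 region: 57 of 61 sites on chromosome 1 plus equalled the mirror position on chromosome 4 minus within 0.001 cDNA. The unit was therefore other than a plain count column, and the absolute value was used as the count.

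The 26 files held 8 distinct tables, 1 for each of 4 groups with unique and multi mapping, and each replicate of a group carried the same copy. Copies were counted once. The description in the labels speaks of 3 summed replicates, while the name of the hnRNP A1 table at ZGA lists 4 libraries and the labels give 4 samples. Which is right was not settled, and n = 4 follows the labels of the samples. Because every group was 1 pooled table, no model was fitted, no replicate was left out and no p-value was computed.

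Sites were compared by nucleotide and strand. Shared sites were set beside the same sites moved by 50 to 500 nt, over 20 draws with seed 20. Clusters joined sites at most 15 nt apart and needed at least 2 sites. Windows were 10 kb on 1 strand, and those with at least 100 hnRNP A1 cDNAs over both stages were compared. The ratio was the window's share of all listed cDNAs at ZGA over that at preZGA, with the exact conditional binomial interval. Shares have exact (Clopper-Pearson) binomial intervals at 95%. Totals of the tables count only listed significant sites and depend on what the filter let through, so numbers of sites, and in part means per site, are given with the main sums. The window code was tested on simulated counts for the 1882 windows of the stage comparison. There, 95.6% of the intervals held the true ratio, the interval excluded 1 in 98% to 100% of windows at each simulated change of 2-fold or 4-fold, and 4.46% of unchanged windows had an interval excluding 1. The simulated counts were Poisson draws, without variation between libraries and without a significance filter on sites. They check the code and do not give the error rate in these data.

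Before the data were examined, the windows to be named were fixed by rule. They were, per stage, the 10 windows with the most hnRNP A1 cDNAs; the 10 highest and 10 lowest stage ratios among windows of at least 100 cDNAs whose interval did not cover 1; and the 5 leading IgG windows per stage. The alternatives fixed then were minimum site counts of 2 and 5 cDNAs, tolerances of 1 and 15 nt, thinning of the larger table, merge distances of 3 and 30 nt, an overlap of 50%, windows of 1 and 100 kb, minimums of 20 and 500 cDNAs, site numbers in place of cDNAs, scaling without the 10 strongest windows, removal of sites near IgG sites, and multi mapping. Scaling to the median window and removal of windows with IgG sites were added after seeing the data. Site numbers in place of cDNAs were first compared over windows of at least 100 sites; after that outcome was seen the windows chosen by cDNAs were used instead, and both outcomes are given. IgG shares and means per site without the chromosome 1 block were also added after seeing the data.

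A genome and annotation of Zv9 were not used here, so windows carry positions and no gene names. Shares by annotation class, ratios per gene, the fixed gene lists and sequence motifs were planned for the case that they could be had and were not analysed here. The gene table of assembly GRCz12tu served only to see which genes neighbour each other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.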

Results

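Crosslink sites of hnRNP A1, an RNA-binding protein known for its part in splicing and other steps of RNA processing, were mapped by iCLIP in zebrafish embryos before zygotic genome activation (preZGA, 32 cells) and during it (ZGA, 1000 cells). Zygotic genome activation is the onset of transcription from the embryo's own genome, and until then the embryo relies on RNA laid down by the mother. In iCLIP, UV light links protein to RNA in the living embryo, the complexes are pulled down with an antibody, and the end of each cDNA marks the crosslinked nucleotide. The 13 libraries fell into 4 groups: hnRNP A1 at preZGA (n = 3), hnRNP A1 at ZGA (n = 4), and an IgG control pull-down at preZGA (n = 3) and at ZGA (n = 3). The deposited tables hold the sum of each group, so each group was 1 pooled table, no spread between replicates could be had, no test was made and no p-value is given. Intervals are exact 95% intervals of the counts and cover counting error only, not the variation between embryo batches. The tables list only sites that passed the submitters' significance filter, so their totals are not the depth of the libraries, and a region without an entry is described as having no significant site listed.

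The hnRNP A1 pull-down gave far more significant sites than IgG at both stages. Uniquely mapped cDNAs gave 287588 hnRNP A1 sites with 583691 cDNAs at preZGA and 200258 sites with 480927 cDNAs at ZGA. IgG gave 1508 sites with 9606 cDNAs at preZGA and 3709 sites with 20262 cDNAs at ZGA. The hnRNP A1 table thus held 191-fold more sites than IgG at preZGA and 54.0-fold more at ZGA, and 60.8-fold and 23.7-fold more cDNAs. The mean was 2.03 cDNAs per hnRNP A1 site at preZGA and 2.40 at ZGA, against 6.37 and 5.46 per IgG site, and 65.4% and 65.1% of hnRNP A1 sites held 1 cDNA. The IgG means rested on 1 block of chromosome 1: without it, a comparison added after seeing the data, they were 2.59 at preZGA and 3.47 at ZGA, against 2.01 and 2.35 for hnRNP A1. The excess over IgG was smaller among stronger sites: with sites of at least 5 cDNAs it was 91.5-fold at preZGA and 18.7-fold at ZGA.

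A single block on chromosome 1 supplied much of the IgG signal. The window at 2600001 to 2610000 on the plus strand (Zv9 coordinates here and throughout) held 5785 IgG cDNAs at preZGA, 60.2% of that table, and 7465 at ZGA, or 36.8%. Nearly all lay from 2600143 to 2600154, with 5477 IgG cDNAs at preZGA. The same window held 6117 hnRNP A1 cDNAs at preZGA and 10381 at ZGA. The fold of hnRNP A1 over IgG cDNAs was 1.06 there at preZGA (1.02 to 1.10) and 1.39 at ZGA (1.35 to 1.43), whereas it was 151 and 36.8 over the rest of the genome. The other leading IgG windows were on chromosome 4 minus at 61290001 to 61300000, with 1766 IgG cDNAs at preZGA and 2812 at ZGA, and on the mitochondrial plus strand at 1 to 10000, with 150 and 1073. At preZGA these were followed by chromosome 4 minus at 52370001 to 52380000 (96 IgG cDNAs beside 176 of hnRNP A1) and at 49790001 to 49800000 (59 beside 45). With unique mapping, a low fold at preZGA was thus not confined to the chromosome 1 block, although the sum over the rest of the genome was high. The window at 49790001 also held 986 hnRNP A1 and 17.2 IgG multi-mapping cDNAs at preZGA, so its low fold is limited to unique mapping. At ZGA the next IgG windows were chromosome 4 plus at 40090001 to 40100000 (577) and chromosome 4 minus at 45690001 to 45700000 (401).

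Few hnRNP A1 sites coincided with an IgG site, but these carried many cDNAs. At preZGA 906 of 287588 hnRNP A1 sites lay on the nucleotide and strand of an IgG site, or 0.315% (0.295 to 0.336), with 8.21% of hnRNP A1 cDNAs. At ZGA the number was 3021 of 200258, or 1.51% (1.46 to 1.56), with 20.9% of cDNAs. Read from the IgG side, 60.1% of IgG sites at preZGA (57.6 to 62.6) and 81.5% at ZGA (80.2 to 82.7) were also hnRNP A1 sites. Allowing 15 nt raised the hnRNP A1 shares to 1.29% and 3.47%.

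The 4 windows with the most hnRNP A1 cDNAs at preZGA, among them the chromosome 1 block, were also among the 10 leading windows at ZGA. Chromosome 4 minus at 61290001 to 61300000 led with 60053 cDNAs over 1421 sites at preZGA, or 10.3% of the table, and 60294 cDNAs over 1316 sites at ZGA, or 12.5%. IgG cDNAs there came to 2.94% of the hnRNP A1 number at preZGA and 4.66% at ZGA. Its log2 share ratio of 0.29 turned to -0.39 without sites within 15 nt of an IgG site. Next came the mitochondrial plus strand at 1 to 10000, with 24387 and 26603 cDNAs and the same top nucleotide, 2300, at both stages. Chromosome 8 plus at 24580001 to 24590000, with no significant IgG site listed at either stage, held 3002 cDNAs at preZGA and 1815 at ZGA, a share ratio of 0.734 (0.692 to 0.778). The other leading preZGA windows each held between 1590 and 1995 cDNAs. They were on chromosome 5 plus at 36190001, 9 plus at 21810001, 12 minus at 34840001, 15 minus at 5790001, 10 plus at 33030001 and 3 minus at 59290001, with at most 3 IgG cDNAs in either table. Their share ratios, ZGA over preZGA, ran from 0.612 on chromosome 9 to 0.915 on chromosome 15. Counted by sites instead of cDNAs, the ratio was above 1 for the windows on chromosomes 8, 5, 15 and 3.

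Crosslink positions were shared between the stages well above the overlap of displaced sites. The question here was whether the listed sites of the 2 stages fell on the same nucleotides. The 73118 nucleotides with a site at both stages were 25.4% of the preZGA sites (25.3 to 25.6) and 36.5% of the ZGA sites (36.3 to 36.7). Sites moved at random by 50 to 500 nt on their strand met a site of the other stage in 4.44% and 6.38% of cases, so the observed overlap was 5.72-fold higher. Moved sites give the overlap by proximity alone, and no overlap between replicates could be had beside it. The excess therefore cannot tell whether hnRNP A1 stayed in place as the embryo's RNA changed. Shared sites were the stronger ones, with 3.63 cDNAs per site at preZGA against 1.48 at the other sites, and 3.92 against 1.53 at ZGA. They held 45.5% of preZGA cDNAs and 59.6% of ZGA cDNAs. Within 15 nt the shares were 64.5% and 75.0%, against 21.5% and 25.6% for displaced sites. Of the clusters, runs of at least 2 sites no more than 15 nt apart, 13071 of 30620 at preZGA (42.7%, 42.1 to 43.2) and 13986 of 26276 at ZGA (53.2%, 52.6 to 53.8) overlapped a cluster of the other stage. A site seen at 1 stage alone is not shown to be absent at the other, since most sites held 1 cDNA.

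Chromosome 4 and the mitochondrial genome took a larger share of hnRNP A1 cDNAs in the pooled ZGA table. Chromosome 4, whose long arm is known to be rich in repeats, had a share ratio of 1.64 (1.62 to 1.65), and the mitochondrial genome 1.45 (1.43 to 1.48). Their shares of IgG cDNAs were higher at ZGA too, at 37.5% against 24.9% for chromosome 4 and 7.98% against 1.56% for the mitochondrial genome. Outside the chromosome 1 block, an alternative chosen after seeing the data, the IgG share of chromosome 4 was instead lower at ZGA, at 59.4% (58.6 to 60.3) against 62.7% (61.1 to 64.2), and that of the mitochondrial genome was 12.6% against 3.93%. The chromosome 4 values depend on the window at 61290001, which was kept here. It held 1766 of the 2395 chromosome 4 IgG cDNAs at preZGA and 2812 of 7607 at ZGA. They therefore do not show a lower IgG share over the rest of chromosome 4. Ratios for chromosomes 1 and 22 were 1.24 (1.21 to 1.26) and 1.09 (1.06 to 1.11). The other 22 chromosomes had lower shares, down to 0.780 on chromosome 19, and the interval lay below 1 for 21 of them. The higher share of chromosome 1 rested on its strongest block: without the 10 windows holding the most cDNAs its log2 ratio was -0.021 instead of 0.31. Without those windows the log2 ratio went from 0.71 to 1.91 for chromosome 4, from 0.54 to 2.83 for the mitochondrial genome and from 0.12 to 0.24 for chromosome 22. The first 2 values rest on a small remainder. At preZGA, 60053 of the 71569 chromosome 4 cDNAs lay in the dropped window at 61290001. Of the 24992 mitochondrial cDNAs, 24387 lay in the dropped plus-strand window. With sites of at least 5 cDNAs the log2 ratio of these chromosomes was 0.27, 0.11 and 0.52. On the mitochondrial plus strand the share went from 4.21% to 5.84%, with 911 and 985 sites. The minus strand went from 404 cDNAs over 134 sites (0.0692%) to 1837 over 194 sites (0.382%). IgG showed no significant minus-strand site at preZGA and 301 cDNAs at ZGA.

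**Figure D1:**
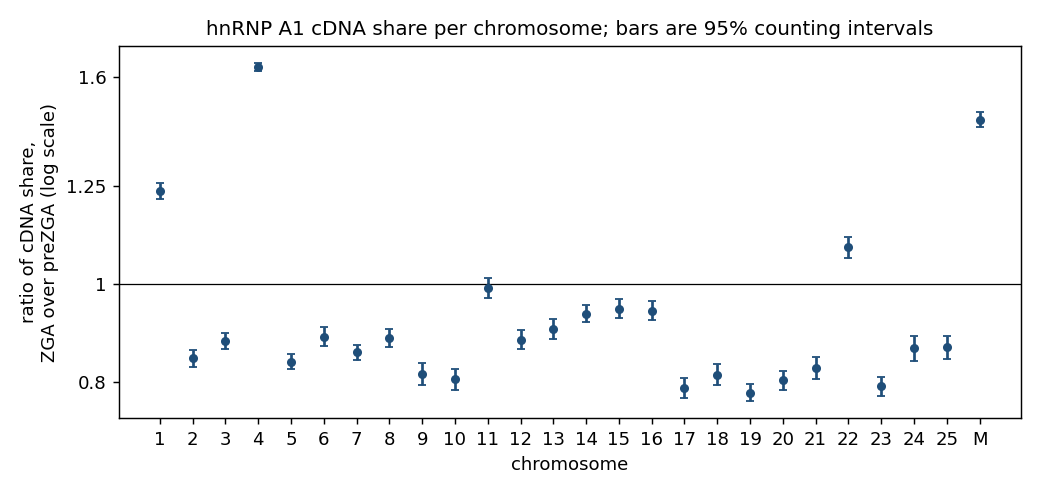
Ratio of the hnRNP A1 cDNA share of each chromosome, ZGA over preZGA, on a log axis; points are the pooled tables and bars the 95% counting intervals. Chromosome 4 (1.64) and the mitochondrial genome, M (1.45), lie highest, and chromosome 19 (0.780) lowest.

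Between the stages, most of the windows compared differed by less than 2-fold in their share of hnRNP A1 cDNAs. Of 19520 windows of 10 kb and 1 strand with a site in any group, 1882 had at least 100 hnRNP A1 cDNAs over both stages and were compared. Of these, 1430 lay within 2-fold, 165 were at least 2-fold higher at ZGA and 287 at least 2-fold lower. The higher windows held 19117 cDNAs over 2724 sites at preZGA (mean 7.02) and 72237 over 7135 sites at ZGA (mean 10.1). The chromosome 1 block, with a ratio of 2.06, was 1 of them and raised both means. It alone supplied 6117 of these cDNAs over 35 sites at preZGA and 10381 over 38 sites at ZGA. The lower windows held 48233 cDNAs over 27248 sites (mean 1.77) and 14532 over 9128 sites (mean 1.59). The median log2 ratio of all 1882 windows was -0.33. Scaled to that median, an alternative chosen after seeing the data, 204 windows were higher and 160 lower, so that the higher ones made up 56.0% of both in place of 36.5%. With no replicate tables, these are differences between 2 pooled tables and not tested changes.

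Windows higher at ZGA often had IgG signal, and windows lower at ZGA seldom did. An IgG site at ZGA lay in 113 of the 165 higher windows, or 68.5% (60.8 to 75.5). It lay in 5.24% (4.15 to 6.53) of the windows within 2-fold and 2.09% (0.771 to 4.49) of the lower ones. The order was the same for IgG sites at preZGA, at 44.8% (37.1 to 52.8), 8.60% (7.20 to 10.2) and 4.88% (2.69 to 8.05). Of the 62 windows at least 8-fold higher, 59 had an IgG site at ZGA, or 95.2% (86.5 to 99.0). In these 62 the IgG cDNAs came to 16.9% of the hnRNP A1 cDNAs at ZGA and 22.7% at preZGA. Chromosome 4 held 55 of the 165, 50 of them beyond 30 Mb. The 52 higher windows without an IgG site at ZGA lay off chromosome 4 in 48 cases. Without windows that held an IgG site at either stage, again chosen after seeing the data, 50 windows were higher and 267 lower.

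**Figure D2:**
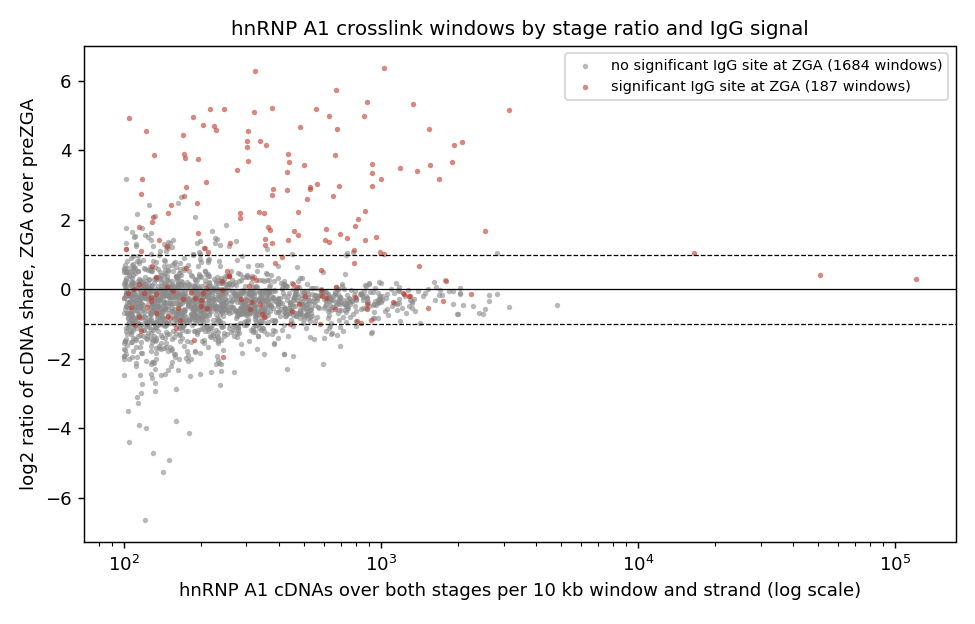
Each point is a 10 kb window on 1 strand, with its hnRNP A1 cDNAs over both stages on a log axis against the log2 ratio of its cDNA share, ZGA over preZGA; dashed lines mark 2-fold. Of the 1871 windows drawn, the 187 with a significant IgG site at ZGA make up most of the upper part, and 11 windows with no site listed at 1 stage are left out.

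Of the 10 windows with the highest ratios, 5 lay on chromosome 4. Chromosome 4 plus at 43570001 to 43580000 went from 15 cDNAs over 8 sites to 1010 over 95 sites, a ratio of 81.7 (49.3 to 147). It held 9 IgG cDNAs at preZGA and 181 at ZGA, or 60% and 17.9% of its hnRNP A1 cDNAs. By sites its log2 ratio was 4.09 instead of 6.35. The other 9 of the 10 highest had no significant hnRNP A1 site listed at preZGA with unique mapping, so no ratio is given; one of them, chromosome 20 plus at 55780001, held 2671 multi-mapping cDNAs at preZGA and 3303 at ZGA. At ZGA the uniquely mapped cDNAs numbered 262 on chromosome 4 plus at 28000001, 206 on 3 plus at 9510001, 201 on 24 plus at 5390001, 192 on 4 minus at 42940001 and 182 on 4 plus at 46860001. In the last 4 they numbered 178 on 20 plus at 55780001, 174 on 4 plus at 50430001, 171 on 8 minus at 41030001 and 155 on 11 minus at 840001. Only the windows at 28000001 on chromosome 4 and 840001 on chromosome 11 had no significant IgG site listed at ZGA with unique mapping, and the former had 162 IgG sites with 21.9 cDNAs with multi mapping. The 201 cDNAs on chromosome 24 came from 3 neighbouring nucleotides, beside 98 IgG cDNAs, and the 155 on chromosome 11 from 8.

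Several windows with large counts at ZGA were also much higher than at preZGA. Chromosome 4 plus at 40090001 went from 104 cDNAs over 19 sites (mean 5.47) to 3051 over 48 sites (mean 63.6), a ratio of 35.6 (29.3 to 43.7), with 577 IgG cDNAs at ZGA. Chromosome 3 minus at 1650001 went from 124 cDNAs over 49 sites (mean 2.53) to 1946 over 145 sites (mean 13.4), a ratio of 19.0 (15.9 to 23.0). Chromosome 4 minus at 45590001 went from 124 over 43 sites (mean 2.88) to 1799 over 151 sites (mean 11.9), a ratio of 17.6 (14.7 to 21.3). The IgG cDNAs of the latter 2 windows at ZGA were 358 and 326. At preZGA the 3 windows held 49, 36 and 46 IgG cDNAs, in the order given. IgG thus came to 47.1%, 29.0% and 37.1% of their hnRNP A1 cDNAs at preZGA, and to 18.9%, 18.4% and 18.1% at ZGA. In these 3 windows every hnRNP A1 site of both stages lay within 15 nt of an IgG site, and in the window at 43570001 all but 8 cDNAs at ZGA did, so no ratio remained without such sites. Counted by sites, the log2 ratio was 1.86 instead of 5.15 at 40090001, 2.09 instead of 4.25 at 1650001 and 2.33 instead of 4.14 at 45590001. Chromosome 4 minus at 45690001 went from 700 cDNAs over 57 sites to 1841 over 145 sites, a ratio of 3.19 (2.92 to 3.49). Its log2 ratio was 1.87 by sites instead of 1.67. Its IgG percentage went the other way, from 2.14% of its hnRNP A1 cDNAs at preZGA to 21.8% at ZGA. Mitochondrial minus at 1 to 10000 went from 166 cDNAs over 59 sites to 1723 over 164 sites, a ratio of 12.6 (10.7 to 14.9), with 267 IgG cDNAs at ZGA. Its log2 ratio was 2.0 by sites and 2.50 without sites near IgG, instead of 3.66. Chromosome 15 plus at 3510001 to 3520000 went from 1042 cDNAs over 180 sites to 1783 over 205 sites, a ratio of 2.08 (1.92 to 2.24), with 4 IgG cDNAs at preZGA and no significant IgG site listed at ZGA. It fell short of 2-fold by sites, at a log2 ratio of 0.71 instead of 1.05. With multi mapping added it was 0.96, and without sites near IgG 1.30. These last 2 settings change the totals, which moves many windows alike: 40090001 on chromosome 4 went from 5.15 to 5.06 with multi mapping added.

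The windows with the lowest ratios were spread over 9 chromosomes and had no significant IgG site listed at either stage. Chromosome 13 plus at 30390001 to 30400000 held 174 cDNAs over 85 sites at preZGA and chromosome 23 minus at 33870001 to 33880000 held 100 over 44 sites, with no significant site listed at ZGA in either. Chromosome 23 plus at 560001 went from 120 cDNAs over 38 sites to 1, a ratio of 0.0101 (0.000254 to 0.0574). The ratio was 0.0262 (0.00534 to 0.0782) for chromosome 3 minus at 17910001, with 139 cDNAs over 67 sites and 3 over 2 sites. Chromosome 21 minus at 18590001 went from 146 cDNAs over 70 sites to 4 over 3, chromosome 11 minus at 10450001 from 126 over 59 to 4 over 3, and chromosome 5 plus at 31480001 from 101 over 45 to 4 over 4. Chromosome 4 plus at 8900001 went from 171 over 91 to 8 over 6, chromosome 20 plus at 35080001 from 116 over 67 to 6 over 6, and chromosome 8 minus at 17240001 from 109 over 38 to 6 over 5.

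A stretch of chromosome 4 from 28000001 to 28020000 carried plus-strand sites at ZGA and none listed at preZGA, in both kinds of mapping. The part from 28010001 was added after its values were seen. Unique mapping gave 176 hnRNP A1 sites with 337 cDNAs at ZGA on the plus strand, and 2 sites with 3 cDNAs on the minus strand. Multi mapping, in which a cDNA is divided over its genomic positions, gave 1114 sites with 1570 cDNAs, or 2.33% of that table. IgG had no significant site listed there with unique mapping, and at ZGA 278 sites with 37.5 cDNAs with multi mapping.

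**Figure D3:**
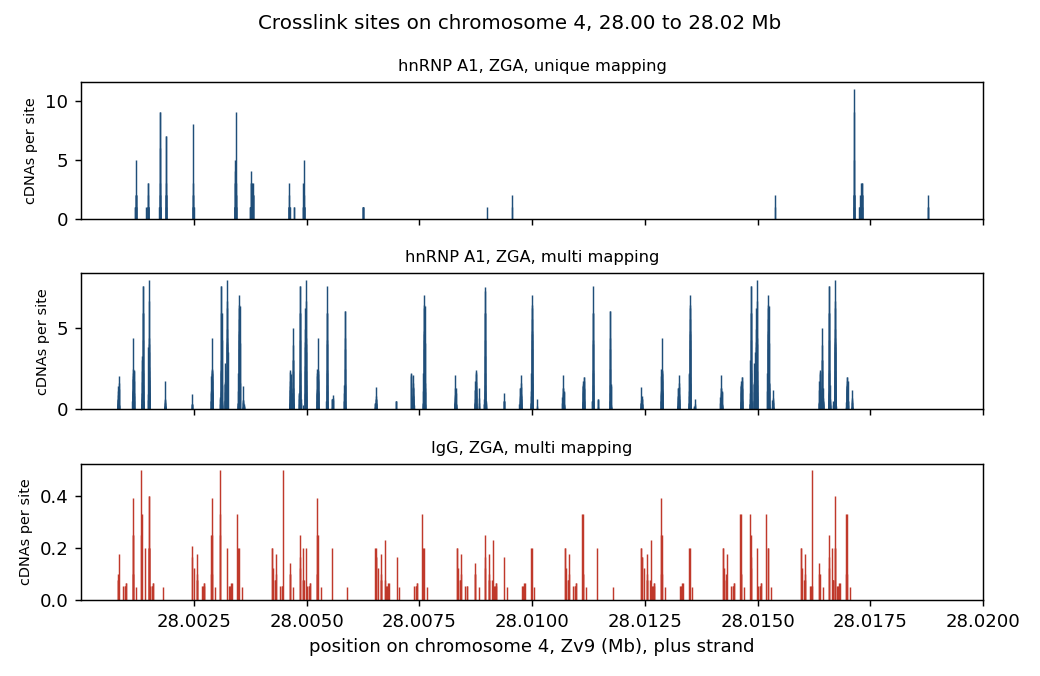
Plus-strand crosslink sites at ZGA on chromosome 4 from 28000001 to 28020000 (Zv9), as cDNAs per nucleotide; each line is 1 site, and the vertical scales differ between panels. hnRNP A1 has 176 sites with unique and 1114 with multi mapping, against 278 weaker IgG sites with multi mapping; no preZGA table lists a site here.

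Multi-mapping cDNAs were more abundant in the pooled ZGA table. hnRNP A1 multi-mapping cDNAs came to 39530 over 61753 sites at preZGA (mean 0.640) and 67522 over 79598 sites at ZGA (mean 0.848), a 1.71-fold difference. Uniquely mapped cDNAs differed the other way, at 0.824-fold. IgG multi-mapping cDNAs were 1775 and 3584. Over both stages together, the leading multi-mapping windows were chromosome 20 plus at 55780001 (2671 and 3303 cDNAs), chromosome 4 minus at 61290001 (1128 and 3931) and chromosome 1 plus at 3370001 (1107 and 3736). The last 2 had a top site of the same value at ZGA, 430.5 cDNAs. The chromosome 1 window had 61 sites at ZGA. In the strand check, 57 of 61 sites on chromosome 1 plus equalled the mirror position on chromosome 4 minus within 0.001 cDNA. The 2 windows may thus hold the same shared cDNAs and should not be read as separate signals. Of 97 windows with at least 100 multi-mapping cDNAs, 25 were at least 2-fold higher at ZGA and 15 at least 2-fold lower. Chromosome 9 plus at 4230001 held more IgG than hnRNP A1 cDNAs at both stages, 679 against 279 at preZGA and 934 against 862 at ZGA.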

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

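No paired analysis was possible because the deposited tables sum the replicates, and for the same reason no replicate could be left out. Alternatives by gene, annotation class, gene list and motif were not run. The 3 alternatives marked as added were chosen after seeing the data, and the cause of each difference was not tested unless the setting itself gives it. With sites of at least 2 cDNAs, hnRNP A1 held 173-fold more sites than IgG at preZGA and 35.9-fold at ZGA; with at least 5 it held 91.5-fold and 18.7-fold. The site number at ZGA over preZGA was 0.701 and 0.819 with these minimums, against 0.696. The percentage of hnRNP A1 sites also in IgG was 0.388 and 0.974 at preZGA and 2.42 and 5.19 at ZGA; it was 1.29 and 3.47 within 15 nt and 2.61 and 3.54 with multi mapping.

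The percentage of preZGA sites shared with ZGA was 37.0 with at least 5 cDNAs, 39.8 within 1 nt, 64.5 within 15 nt and 27.9 with the larger table thinned and at least 2 cDNAs in both. That of ZGA sites was 36.2 and 45.2 with at least 2 and 5 cDNAs, 53.8 within 1 nt, 75.0 within 15 nt and 31.9 with both thinning and that minimum of 2. For clusters, preZGA gave 41.6% and 45.6% with at least 2 and 5 cDNAs, 33.3% with a merge distance of 3 nt and 28.2% with an overlap of 50%. ZGA gave 56.0% and 56.9%, 47.5%, 52.2% with a merge distance of 30 nt, and 43.1% with an overlap of 50%.

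The log2 ratio of chromosome 4 stayed above 0, at 0.62 and 0.27 with at least 2 and 5 cDNAs, 0.93 by sites and 1.91 without the 10 strongest windows. For the mitochondrial genome it was 0.44, 0.11, 0.70 and 2.83 in the same order, and for chromosome 22 it was 0.17, 0.52, 0.055 and 0.24. Dropping the strongest windows took out most cDNAs of chromosome 4 and of the mitochondrial genome. Chromosome 1 gave 0.37 and 0.43 with these minimums, but turned to -0.0056 by sites and -0.021 without the strongest windows.

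Windows at least 2-fold higher at ZGA numbered 790 and 47 with minimums of 20 and 500 cDNAs, since more or fewer windows enter, 92 without sites near an IgG site, 50 without windows holding an IgG site (added), 33 by sites over windows of at least 100 sites, and 149 by sites over the windows chosen by cDNAs (added). Lower windows numbered 1340 and 18 with these minimums, 63 by sites over windows of at least 100 sites, 154 by sites over the windows chosen by cDNAs (added), 173 without sites near IgG and 160 scaled to the median window (added). The percentage of higher windows with an IgG site was 22.9 and 93.6 with minimums of 20 and 500, 13.0 without sites near IgG, 79.1 with multi mapping added and 57.4 scaled to the median (added). The 13.0 is lowered by the removal itself, which takes out the hnRNP A1 sites beside IgG sites. It is therefore no check of this percentage. Multi-mapping cDNAs at ZGA over preZGA came to 1.98 with sites of at least 2 cDNAs. Of 74 alternative values for the 27 named windows with a ratio, 68 kept their direction, leaving out the rescalings, which move every window by the same amount. The alternatives kept also change the totals, so part of each move is common to many windows. Chromosome 9 plus at 21810001, with no significant IgG site listed, went from -0.71 to -0.43 without sites near IgG. The 68 values are thus no separate check of each window. Without sites near IgG, 7 of the 27 named windows had no ratio, since no preZGA site was left: the chromosome 1 block, chromosome 3 minus at 1650001, and on chromosome 4 those at 40090001, 43570001, 45590001, 45690001 and 52370001. Their higher values thus have no check by this alternative. Chromosome 4 minus at 61290001 turned to -0.39 without sites near IgG. By sites, chromosome 8 plus at 24580001 turned to 0.32, 5 plus at 36190001 to 0.034, 3 minus at 59290001 to 0.012 and 15 minus at 5790001 to 0.27. The window at 5790001 also turned to 0.16 without sites near IgG, and scaling to the median (added) puts it at 0.20. The median scaling is a shift common to all windows. The rise without sites near IgG was close to that of chromosome 9 plus at 21810001. Neither value thus says anything of the window at 5790001 alone. Low counts limit single sites, since most uniquely mapped hnRNP A1 sites hold 1 cDNA.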

Other observations

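All tests in this part were chosen after the values they bear on had been seen. On chromosome 4, pairs of windows on opposite strands carried nearly equal multi-mapping counts; each such cDNA is divided over its positions, so near-identical copies share their counts. At ZGA, hnRNP A1 held 1426 cDNAs on the plus strand at 44010001 and 1426 on the minus strand at 43900001, and 1537 at 43980001 plus against 1478 at 43920001 minus. Chromosome 5 minus at 4380001 held 1351 and chromosome 4 minus at 49790001 held 1394. IgG held between 9.17 and 12.6 cDNAs in each of these windows at ZGA.

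The windows at least 2-fold higher at ZGA carried IgG signal far more often than the others. At ZGA an IgG site lay in 68.5% of them against 5.24% of those within 2-fold, and at preZGA in 44.8% against 8.60%. Among windows within 2-fold weighted to the same ZGA cDNA numbers the share at ZGA was 8.96%. The number of cDNAs alone thus did not account for the 68.5%. Cross-mapping between near-identical copies stays open: 92.7% of the windows stayed at least 2-fold higher once multi-mapping cDNAs were added, but 115 of the 165 have no such cDNA listed, which leaves little to add. Background RNA recovered with either antibody may account for part of the higher windows, while the 52 without an IgG site at ZGA are left open. A larger amount of these RNAs in the ZGA embryo, the biological explanation the stages give, was not tested, since no RNA abundance was analysed here.

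The block at 2600143 on chromosome 1 had nearly as many IgG as hnRNP A1 cDNAs, 1.06-fold at preZGA and 1.39-fold at ZGA. The strongest hnRNP A1 window, chromosome 4 minus at 61290001, showed 34.0-fold and 21.4-fold. The block was picked for its IgG cDNAs and that window for its hnRNP A1 cDNAs, a choice that favours such a difference. Whether the block holds the same kind of background as that window is therefore left open. A molecule carried in like amount into libraries of both antibodies is a candidate explanation, and where it comes from is open. No biological explanation was tested.

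The stretch of chromosome 4 from 28000001 to 28020000 carried multi-mapping values that recurred along it, with the highest autocorrelation, 0.345, at 1741 nt and a lower one, 0.180, at 3503 nt. Each multi-mapping cDNA is placed at every copy of its sequence, so this describes repeats in the genome and says nothing of how they are transcribed. Background RNA stays open for it: IgG came to 2.39% of hnRNP A1 cDNAs at ZGA with multi mapping, beside a median of 2.36% in 23 other multi-mapping windows that were higher at ZGA, although it was below the 16.9% of the uniquely mapped windows at least 8-fold higher. A hypothesis for its identity is the miR-430 cluster, precursors of a microRNA family known for clearing maternal mRNA; the GRCz12tu gene table has 58 mir430 genes, 46 of them in 1 run of neighbours. That table is of another assembly, so the identity is left open.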
